A study of Mus musculus with 12 samples.

How the data were processed

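MicroRNA levels were measured by array in ventricular heart tissue of 12 C57Bl/6J mice. The labels' protocols record hearts snap frozen after collection at ZT 6, which is 6 hours into the light phase, total RNA from a miRNeasy extraction, and biotin labelling by an Affymetrix procedure. The labels divide the mice into 4 groups of 3 by genotype (wild type or homozygous Clock mutant) and age (4 or 21 months), and call the replicates biological, so each array was counted as 1 animal.

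The deposited values are a table of 3163 probe sets by 12 arrays, on a scale taken here as log2. In all 3163 probe sets the median over the 12 arrays is 0 to within a tolerance of 1e-06, so the authors expressed each probe set relative to its own median. That centring cancels in any difference between groups, but it removes the absolute signal: no level, detection call or background remains, and one probe set's level cannot be set against another's. The base of the logarithm, the background correction and the normalization between arrays are not given in the sources used here. If the base were other than 2, the folds below would change and the tests would not. No value was missing, and every column of the table was used.

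Probe sets carry miRBase accession numbers. By their prefix, 1908 (MIMAT) are for mature miRNAs and 1255 (MI) for hairpin precursors. The table does not pair these with miRNA names, and 0 of the IDs matched the mouse gene table that was used for names. MiRNAs are therefore given by ID only, with at most 2 IDs higher and 2 lower in each comparison, and their genomic positions are not reported. For the same reason none of the 16 miRNA lists fixed before the data were examined (heart muscle, hypertrophy, fibrosis, ageing, clock-linked, cell type markers and others) was tested.

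The tests compared group means in limma 3.58.1 (R 4.3.3). One linear model with a mean per group was fitted to all 12 arrays over the 1908 mature probe sets, leaving 8 residual degrees of freedom, and the variances were moderated by empirical Bayes (prior degrees of freedom 2.82). There were 7 contrasts: Clock against wild type at each age, 21 against 4 months in each genotype, the genotype by age interaction, and the genotype and age differences averaged over the other factor. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast. A filter on mean signal had been planned, but values centred per probe set do not allow one, so all mature probe sets were tested. The rule for named miRNAs, fixed before the data were examined, took, for a comparison of 2 groups, up to 10 called rises and 10 called falls by size and then the smallest unadjusted p until 10 were named, and for the other contrasts the 5 smallest p. It was shortened to the limit on IDs given above.

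The similarity of the genotype differences at both ages, and of the age differences in both genotypes, was measured as a correlation across probe sets, which are not independent replicates. Added after seeing the data were the share of the total variance of the mature probe sets that each factor took, the first principal component, and the separate tests of precursor probe sets. These single values have exact permutation p-values over the 400 exchanges of genotype labels within each age, or of age labels within each genotype. They are two-sided for the correlations and the first principal component. For a variance share the p is the fraction of exchanges with at least as large a share. For the interaction these exchanges assume no genotype effect at either age, so its p does not test whether the genotype effects are equal. The 6 such tests over mature probe sets form 1 family for Benjamini-Hochberg adjustment. Permutation tests of precursors, and of mature against precursor probe sets, lie outside it and were not adjusted.

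The fit was tested on simulated data with the spread of the real probe sets, 200 of 1908 of them changed, in 20 draws. For 21 against 4 months in Clock mice, 17.6% of changes of 0.5 on the log2 scale were recovered, 72.8% of changes of 1 and 96.3% of changes of 2, with 3.93% false calls. For the age difference averaged over genotypes these shares were 47.1%, 90.5% and 99.6%, with 4.86% false calls. The draws gave each probe set independent noise and every array the same precision, which the real arrays need not share. With 200 changes present, the adjusted threshold is also looser than with few. These shares may therefore be too favourable for a few changed miRNAs in the real data. The number of arrays, 3 per group, limits the precision.

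Alternatives were quantile normalization, median centring of each array, array weights, the replicate number as a block, only the groups compared, precursors tested too, a threshold of 0.10, and leaving out each array. Quantile normalization was applied to the values relative to each probe set's median. It gives the arrays the same distribution of these values, so it removes any net rise or fall between arrays by construction, whatever its cause. A robust variance estimate without the planned intensity trend, adjustment over the more variable probe sets only, quantile normalization of the precursors, and leaving out together the 3 arrays lowest on the first principal component, were chosen after seeing the data.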

Results

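The study compared cardiac miRNAs between wild-type mice and mice homozygous for the Clock Δ19 mutation, in young and old animals. CLOCK is a core transcription factor of the circadian clock, and this mutant form impairs the molecular rhythm. Ventricles of 12 mice were profiled, 3 from each combination of genotype and age (4 or 21 months), all taken at ZT 6. The design allows the effect of genotype at each age, the effect of age in each genotype, and the dependence of either on the other to be examined. All these comparisons hold for ZT 6 only, and rhythms over the day could not be examined. Values were levels on a scale taken as log2, of each probe set relative to its median over the 12 arrays. The array medians over the 1908 mature miRNA probe sets lay between -0.02 and 0.03. The standard deviation across these probe sets ranged from 0.317 in Clock 21-month replicate 1 to 0.521 in Clock 21-month replicate 2. The Clock transcript is not a miRNA, so the genotype labels were not checked against the values.

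The arrays separated by age along the axis of largest variance. The first principal component of the mature miRNA probe sets held 21.3% of the variance, and all 6 hearts of 21 months (2.34 to 8.68) lay above all 6 hearts of 4 months (-14.0 to 1.96). Clock 4-month replicates 2 and 3 and WT 4-month replicate 2 stood apart at -11.8, -14.0 and -10.7, while the other 3 young hearts (-1.73, -0.888 and 1.96) lay closer to the old ones and still below each of them. The mean difference between ages was 12.4 units (exact permutation p = 0.005, the smallest the 400 exchanges can give; adjusted p = 0.015 over 6 tests). Age took 17.1% of the total variance against a median of 8.38% in the other exchanges (exact permutation p = 0.005, adjusted p = 0.015). With those 3 young hearts left out together, the age share was 15.2% (exact permutation p = 0.275). They were chosen as the farthest from the old hearts, and their removal leaves 1 Clock heart of 4 months and 40 exchanges, so a weaker separation was built in. Fewer arrays also raise the share that chance gives, so 15.2% and 17.1% are not directly comparable. Genotype took 10.4% against a median of 8.06% (exact permutation p = 0.065, adjusted p = 0.078), and the interaction took 7.51% (exact permutation p = 0.76). Correlations between arrays were taken on values relative to each probe set's median, which removes the differences in level between probe sets. Their median was 0.0664 between arrays of the same group and -0.0749 between arrays of different groups. Such correlations are low by construction and do not measure how well replicate arrays reproduced each other in level. Clock 21-month replicate 2 lay at -21.0 on the second component (16.1% of the variance), 19.5 units from the nearest array, while the other 11 arrays spanned 6.92 units.

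**Figure D1:**
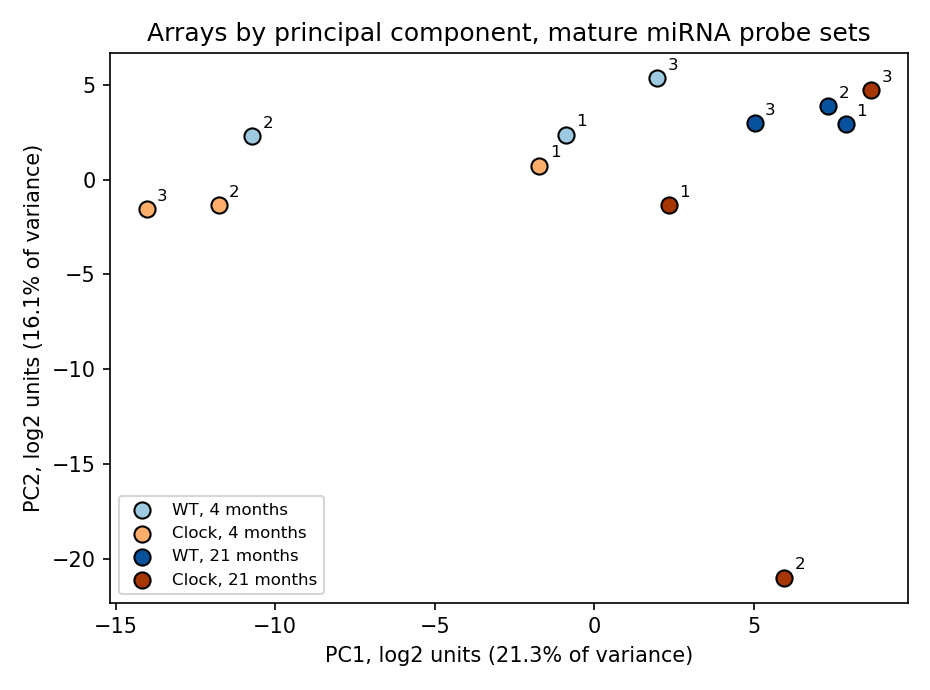
Each point is 1 of the 12 arrays, placed by its first (x axis, 21.3% of variance) and second (y axis, 16.1%) principal component of the 1908 mature miRNA probe sets, in log2 units, coloured by group and numbered by replicate. The 21-month hearts lie to the right of the 4-month hearts, and Clock 21-month replicate 2 lies at -21.0 on the second component.

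At 4 months, no mature miRNA differed between Clock and wild-type hearts after adjustment (limma, 0 of 1908; smallest adjusted p = 0.142). At an unadjusted p under 0.05 there were 56 higher and 59 lower in Clock, 115 in all, where chance gives 95.4. The total ranged from 85 (without Clock 4-month replicate 2) to 145 when each array was left out, with 37 higher without WT 4-month replicate 1 and 39 lower without Clock 4-month replicate 3. The smallest p belonged to MIMAT0000657_st, which was at -0.93 ± 0.063 in Clock and 0.17 ± 0.11 in wild type (log2 relative to the probe set's median, SD, n = 3), a difference of -1.10 (SE 0.18), or 2.14-fold lower in the mutant. The next lower one, MIMAT0027951_st, differed by -0.81 (SE 0.18), and the 2 higher ones with the smallest p, MIMAT0012771_st and MIMAT0004889_st, by 0.95 (SE 0.20) and 0.65 (SE 0.15). Each of these 3 had an adjusted p of 0.604. The 95% confidence interval of the difference excluded a 2-fold change in either direction for 1480 probe sets (77.6%). Its median half-width was 0.466 on the log2 scale. Here and in the contrasts below, such counts include probe sets that may lie at background, since no signal filter was possible. They are therefore not shares of expressed miRNAs. The groups did not overlap at 11.1% of probe sets, where chance gives 10%. Without WT 4-month replicate 1, 1 miRNA passed.

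At 21 months, again 0 of 1908 mature miRNAs passed for genotype (limma, smallest adjusted p = 0.382), with 62 higher and 50 lower in Clock at an unadjusted p under 0.05. That balance moved with single arrays, to 55 and 29 without WT 21-month replicate 2, 49 and 55 without WT 21-month replicate 1, and 50 and 59 without WT 21-month replicate 3. MIMAT0000679_st was at 0.19 ± 0.33 in Clock and 0.96 ± 0.13 in wild type (SD, n = 3), a difference of -0.76 (SE 0.17). MIMAT0028400_st differed by -1.195 (SE 0.28). MIMAT0004670_st (1.03, SE 0.24) and MIMAT0004529_st (0.51, SE 0.11) were higher in Clock. All 4 had an adjusted p of 0.382. MIMAT0004670_st was at 0.13 ± 0.15 in Clock and -0.90 ± 0.58 in wild type. Its difference ranged from 0.74 (without WT 21-month replicate 1) to 1.31 when each array was left out. The wild-type values of MIMAT0004670_st and MIMAT0000679_st also enter their age differences below. The interval of the difference excluded a 2-fold change for 1461 probe sets (76.6%).

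Averaging the genotype difference over both ages gave no call either (limma, 0 of 1908; smallest adjusted p = 0.161), with 55 higher and 62 lower at an unadjusted p under 0.05. MIMAT0000657_st had the smallest p here too, with a difference of -0.76 (SE 0.13), made up of -1.10 at 4 months and -0.43 at 21 months. MIMAT0005443_st was lower in Clock by a similar amount at each age, -0.78 and -0.95 (average -0.86, SE 0.17, adjusted p = 0.343). MIMAT0017000_st was 0.71 higher on average (SE 0.16, adjusted p = 0.354). With the smaller error of the average, a 2-fold difference was excluded for 1720 probe sets (90.1%). Across the mature probe sets, the genotype differences at 4 and 21 months correlated weakly (r = 0.161, Spearman's rho = 0.124, exact permutation p = 0.06, adjusted p = 0.078). The 2 sets of differences share no array.

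In wild-type hearts, 1 mature miRNA rose with age. MIMAT0028056_st went from -0.61 ± 0.11 at 4 months to 0.85 ± 0.10 at 21 months (SD, n = 3), a rise of 1.45 (SE 0.20) or 2.74-fold (limma, adjusted p = 0.039). MIMAT0000679_st, which was at -0.076 ± 0.050 at 4 months and 0.96 ± 0.13 at 21 months, was next (1.03, SE 0.17), with an adjusted p of 0.0803. The largest evidence for a lower level with age was for MIMAT0004670_st (-1.01, SE 0.24) and MIMAT0027774_st (-1.09, SE 0.28), both with an adjusted p of 0.363. At an unadjusted p under 0.05, 78 were higher and 29 lower at 21 months, where chance gives 47.7 in each direction. After quantile normalization these counts were 71 and 66, and without WT 21-month replicate 1 they were 76 and 19. The MIMAT0028056_st call did not pass after quantile normalization (adjusted p = 0.0679), and of the 12 fits that left out 1 array it passed only without Clock 21-month replicate 2 or 3 (adjusted p = 0.0025 and 0.00625). In the other 10 the adjusted p reached 0.255, with a difference between 1.40 and 1.52 over all 12.

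In Clock hearts, 2 mature miRNAs rose with age. MIMAT0000134_st rose from -1.495 ± 0.58 to 1.44 ± 0.77 (SD, n = 3), a change of 2.93 (SE 0.44) or 7.62-fold (limma, adjusted p = 0.0372). MIMAT0003475_st rose from -1.59 ± 0.33 to 0.70 ± 0.47, a change of 2.29 (SE 0.32) or 4.89-fold (adjusted p = 0.037). MIMAT0025103_st (-1.06, SE 0.23, adjusted p = 0.173) and MIMAT0000597_st (-1.09, SE 0.29, adjusted p = 0.244) were lower at 21 months without passing. At an unadjusted p under 0.05, 118 were higher and 70 lower, against 83 and 94 after quantile normalization and 53 and 66 without the 3 young hearts that stood apart, a removal that leaves 1 young Clock heart. Neither rise passed in a fit to the 6 Clock arrays alone (adjusted p = 0.248 and 0.223). The same held without Clock 21-month replicate 2 (changes of 2.55 and 2.05, adjusted p = 0.0692 and 0.0559). Over the 12 fits that left out 1 array, the change of MIMAT0000134_st lay between 2.55 and 3.33. That of MIMAT0003475_st lay between 2.05 and 2.52. Leaving out each array in turn ended the MIMAT0000134_st call in 8 of 12 fits (all but those without a WT 4-month array or Clock 21-month replicate 3; adjusted p up to 0.191) and the MIMAT0003475_st call in 7 (all but those without a WT 4-month array, Clock 21-month replicate 1 or WT 21-month replicate 3; adjusted p up to 0.191).

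**Figure D2:**
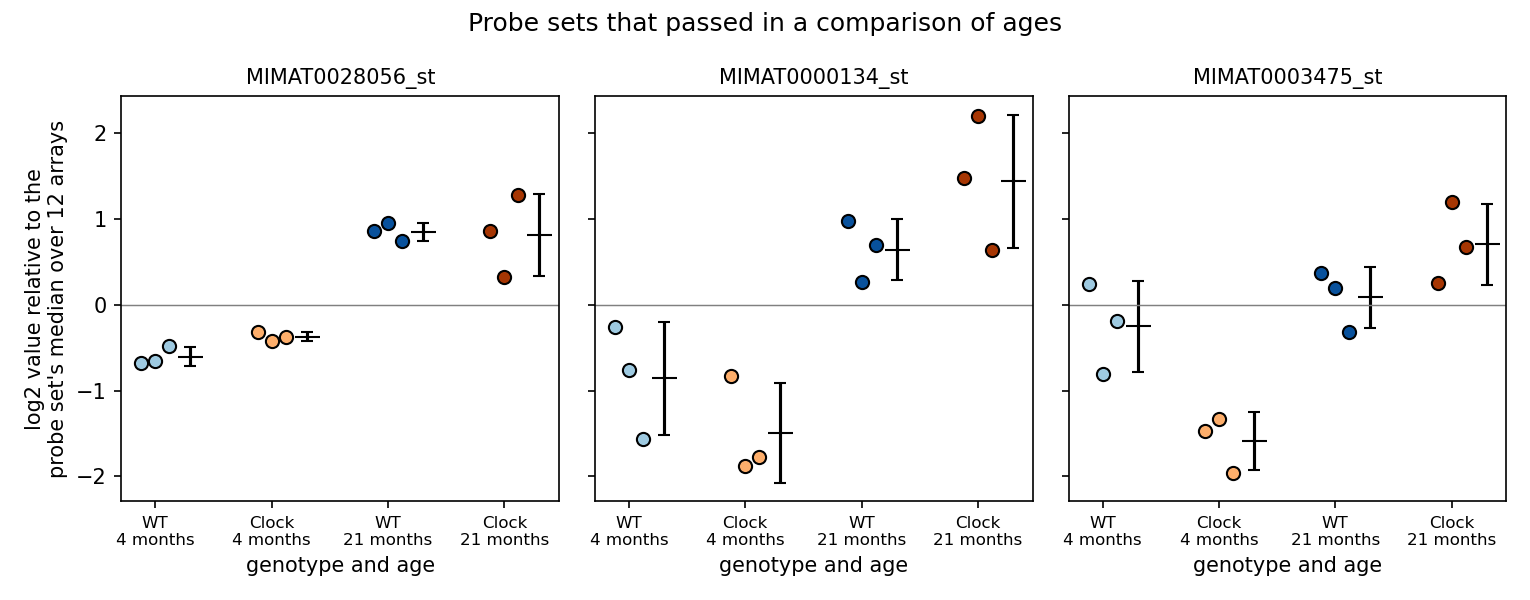
Log2 values of the 3 mature miRNA probe sets that passed in a comparison of ages (y axis, relative to each probe set's median over 12 arrays), by genotype and age (x axis). Points are the 3 arrays of each group and bars the mean ± SD. MIMAT0028056_st and MIMAT0000134_st are higher in every 21-month heart than in every 4-month heart, and MIMAT0003475_st is at -1.59 in young Clock hearts.

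Averaged over genotypes, 2 mature miRNAs rose with age and 0 fell. MIMAT0028056_st rose by 1.32 (SE 0.14) or 2.50-fold (limma, adjusted p = 0.00367) and was higher in each of the 6 old hearts than in each of the 6 young hearts. Its difference between ages in Clock hearts alone was 1.19 (SE 0.20, adjusted p = 0.0563). MIMAT0000134_st rose by 2.21 (SE 0.31) or 4.64-fold (adjusted p = 0.0206). Its difference in wild-type hearts alone was 1.496 (SE 0.44, adjusted p = 0.467). The MIMAT0028056_st call held without any 1 array (adjusted p up to 0.0211). The MIMAT0000134_st call ended without Clock 4-month replicate 2 or 3 or WT 21-month replicate 1 or 3 (adjusted p up to 0.0869). Its difference lay between 2.025 and 2.412 when each array was left out in turn. At an unadjusted p under 0.05, 145 were higher and 65 lower at 21 months, 210 in all against 95.4 by chance. The counts of higher and lower were 128 and 71 after centring each array on its median, and 106 and 90 after quantile normalization. The smaller excess after quantile normalization was built in, so it does not show whether the excess came from scaling. Without the 3 young hearts that stood apart, 70 were higher and 68 lower, and 0 miRNAs passed in this contrast or in either genotype. MIMAT0028056_st and MIMAT0000134_st then differed by 1.28 (adjusted p = 0.32) and 1.91 (adjusted p = 0.427), in a comparison with fewer young hearts. The number of calls moved with the processing, to 13 with array weights, to 6 without Clock 21-month replicate 2, and to 4 without WT 4-month replicate 1 or 3 or Clock 21-month replicate 1, each including both miRNAs named here.

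No miRNA passed the test of whether the effect of age differed between genotypes (limma interaction, 0 of 1908 called; smallest adjusted p = 0.538; 80 with an unadjusted p under 0.05, against 95.4 by chance, and 63 to 108 when each array was left out). MIMAT0003475_st had the smallest p. Its difference between ages was 0.34 (SE 0.32) in wild type and 2.29 in Clock, and these differed by 1.95 (SE 0.45). MIMAT0003469_st differed by 1.64 (SE 0.40), MIMAT0027695_st by -0.85 (SE 0.20) and MIMAT0025087_st by -0.98 (SE 0.24). All 4 had an adjusted p of 0.538. Intervals were wider for this contrast, with a median half-width of 0.659, and excluded a 2-fold difference between the age effects for 1108 probe sets (58.1%). The age differences in the 2 genotypes, which share no array, correlated across mature probe sets (r = 0.375, Spearman's rho = 0.244, exact permutation p = 0.01, the smallest the exchanges can give; adjusted p = 0.02). The correlation was 0.218 (exact permutation p = 0.01) without WT 4-month replicate 2 and 0.146 (exact permutation p = 0.025) without the 3 young hearts that stood apart.

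**Figure D3:**
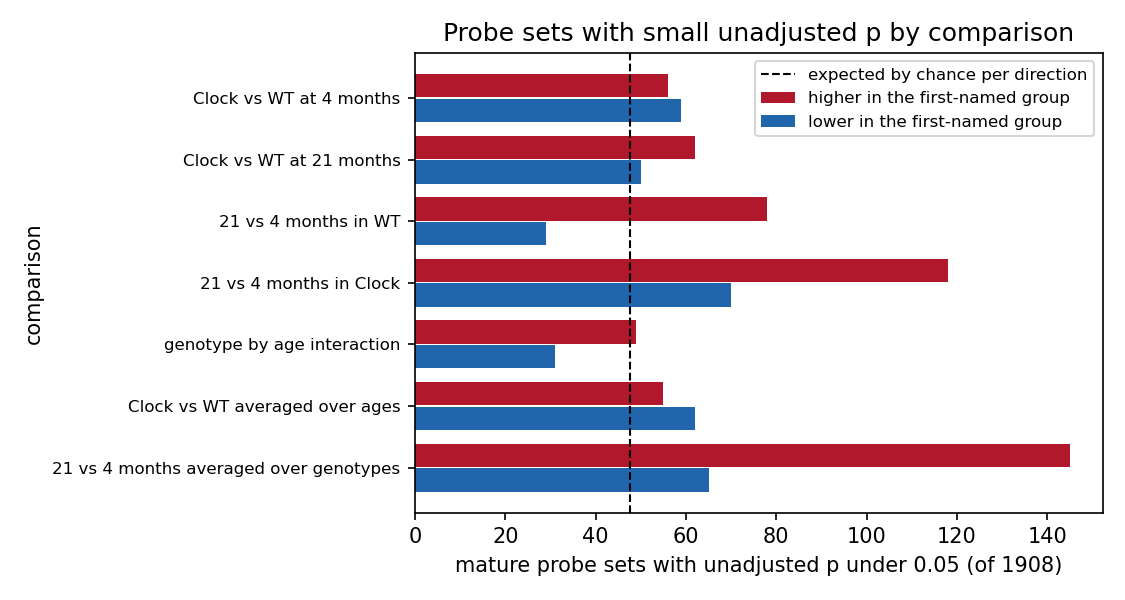
Number of the 1908 mature miRNA probe sets with an unadjusted p under 0.05 (x axis) in each of the 7 contrasts (y axis), split by direction; for the interaction, higher means a larger Clock minus wild-type difference at 21 months. The dashed line marks the 47.7 per direction that chance gives. The averaged age contrast has 145 higher and 65 lower. After quantile normalization, which removes net shifts between arrays by construction, these were 106 and 90.

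The 1255 precursor probe sets, tested separately, gave 0 calls in each of the 7 contrasts (limma, smallest adjusted p = 0.0546, for 21 against 4 months in Clock). After quantile normalization 4 precursors passed for age averaged over genotypes and 0 in the other contrasts. At an unadjusted p under 0.05 the averaged age contrast had 30 higher and 75 lower at 21 months, against 40 and 56 after quantile normalization. The other contrasts had 28 to 43 higher and 33 to 66 lower. Age took 12.5% of the variance of these probe sets (exact permutation p = 0.005, added after seeing the data).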

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

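The test in this part was chosen after the data were seen. Over the 1255 precursor probe sets, the genotype by age interaction took 9.79% of the variance, against a median of 8.70% in the other exchanges of genotype labels within each age (exact permutation p = 0.035). It drew attention because its p was under 0.05 here and not over mature probe sets, where the share was 7.51% (exact permutation p = 0.76). The exchanges assume no genotype effect at either age, so this p does not test whether the effects at the 2 ages are equal. The genotype differences at 4 and 21 months had a correlation of -0.062 over precursors (exact permutation p = 0.16). Leaving out each array in turn gave shares from 10.1% to 11.6% with exact permutation p from 0.01 to 0.22, and 6 of the 12 removals took p to 0.05 or more: Clock 4-month replicate 2 (p = 0.13, exact), WT 4-month replicates 1 (0.215) and 3 (0.22), Clock 21-month replicate 2 (0.095), and WT 21-month replicates 2 (0.115) and 3 (0.14). Fewer arrays raise the share that chance gives, so shares above 9.79% are not a stronger pattern. No single precursor passed for the interaction (limma, smallest adjusted p = 0.516, with 28 higher and 35 lower at an unadjusted p under 0.05). The permutation p of 0.035 is one of several tests of variance shares and was not adjusted for them. No explanation was tested.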

How the results depend on the processing

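The adjustment over the more variable probe sets, the removal of 3 arrays together, the robust variance estimate and the variance shares with their alternatives were chosen after seeing the data. The counts of 0 for genotype at 21 months, for genotype averaged over ages and for the interaction remained 0 under every alternative that was run, and genotype at 4 months gave 0 to 1 calls when each array was left out. The calls for age moved. In wild type, 1 call became 0 after quantile normalization or with the replicate block, and 2 with array weights, at an adjusted p under 0.10, or adjusted over the more variable probe sets. Leaving out each array gave 0 to 2 calls, and the 1 call without WT 4-month replicate 1 or 2 was of another miRNA. In Clock, 2 calls became 0 with only the groups compared, 1 with the replicate block, and 4 at an adjusted p under 0.10 or over the more variable probe sets. Counts were 0 to 5 when each array was left out, with none of the original 2 among the 2 calls without Clock 21-month replicate 2. Averaged over genotypes, 2 calls became 13 with array weights, 5 with the replicate block (3 higher, 2 lower), and 17 (15 higher, 2 lower) at an adjusted p under 0.10 or over the more variable probe sets, and 1 to 6 when each array was left out. Without the 3 arrays lowest on the first component (Clock 4-month replicates 2 and 3, WT 4-month replicate 2), a removal that builds in a weaker separation and leaves a lone Clock 4-month array, assumed to vary like the others, the age calls were 0 in each genotype and 0 averaged, the age share 15.2% (exact permutation p = 0.275) and the first component difference 3.80 (exact permutation p = 0.6). A looser threshold raises counts by construction, and of the other changes the cause was not tested. No fold change reversed, but named miRNAs were picked as extremes. Here 39 values lost a call, 5 gained one and 480, mostly uncalled, did neither. The replicate numbers do not pair the animals: same-numbered arrays of different groups had residual correlations from -0.107 to 0.116, over 0.1 in 2 of 18 pairs, and 5 of 12 arrays correlated best with their own number. A block leaves the correlations of effects as they are in this balanced design. When each array was left out, the correlation of genotype effects ranged from 0.109 to 0.193 (exact permutation p from 0.01 to 0.17, under 0.05 without Clock 4-month replicate 2, WT 4-month replicate 1 or Clock 21-month replicate 3), and the variance share of genotype from 9.95% to 13.2% (p from 0.01 to 0.175, under 0.05 without Clock 4-month replicate 1, WT 4-month replicate 2 or Clock 21-month replicate 3). The correlation of age effects ranged from 0.218 (without WT 4-month replicate 2) to 0.410, with exact permutation p up to 0.03. Fewer arrays raise the share that chance gives, so a share with arrays left out is not directly comparable with the full one. The share of the interaction was 9.79% over precursors. The filters on mean signal, the intensity trend and all tests of miRNA lists were not run, for want of signal levels and names. Without signal levels, dim probe sets were not separated from expressed ones.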

Other observations

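The tests of mislabelled age, of quantile normalization, of 3 young arrays together and of mature against precursor probe sets, the description of joined precursor sets, and the margin required of the precision of 1 array were chosen after the result was seen, and the other tests after a first fit and principal components but before their own values. Mature probe sets were on average 0.0648 higher and precursor probe sets were on average lower (difference of -0.0222 on the log2 scale) at 21 than at 4 months, which sets them 0.087 apart. As array means, mature minus precursor ran from -0.0905 to 0.00191 in young hearts and from 0.000779 to 0.106 in old hearts. The lowest were Clock 4-month replicates 2 and 3 (-0.0804 and -0.0905) and WT 4-month replicate 2 (-0.0655), the same young arrays that lay lowest on the first component, and without these the difference between ages was 0.0498. A shift of a whole array cannot account for the difference, by construction, and the exact permutation p of 0.01 bears only on chance. With all probe sets quantile normalized together the difference was 0.0751 (exact permutation p = 0.005). A shift in miRNA processing with age, and a normalization that treats dim and bright probe sets differently, both stay open and were not tested.

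Among precursors in Clock hearts, 14 had an adjusted p under 0.10 between ages (10 higher at 21 months), but they came from 7 distinct signals when probe sets correlated above 0.99 were joined. The largest of these joined sets held 6 probe sets, each with the _x_st suffix that marks probes shared with other sequences. Its median value was -0.354 ± 0.055 at 4 months and 0.461 ± 0.184 at 21 months in Clock, and 0.00469 ± 0.196 and 0.177 ± 0.370 in wild type (SD, n = 3). Its adjusted p was 0.0546 in Clock, at least 0.935 in wild type and at least 0.784 for the interaction, so a difference between genotypes was not shown.

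The separation of old from young hearts over mature probe sets did not rest on 1 array: without each array in turn, the exact permutation p of the age share of variance was at most 0.01. Whether it rests on 3 young arrays together, Clock replicates 2 and 3 and WT replicate 2 (-11.8, -14.0 and -10.7 on the first component), which correlated with one another at 0.284 to 0.330, stays open: leaving them out gave an age share of 15.2% (exact permutation p = 0.275), but removing the arrays farthest from the old ones weakens the separation by construction. After quantile normalization the age share was 16.3% against 17.1% before, with an exact permutation p at the smallest possible value both times (0.005). Different distributions of the relative values between arrays are thus argued against as the whole cause, but not as a part of it. Differences in the intensity distributions of the arrays stay open, because the normalized values hold no absolute signal. Centring each array (exact permutation p also 0.005) decides nothing about scaling, because the array medians were already near 0. The labels give no array batch, so a difference in handling between the ages, such as storage or hybridization day, or one shared by those 3 arrays, cannot be weighed against age itself.

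Clock 21-month replicate 2 lay apart from the other 11 arrays. Its first component value of 5.95 lay outside the range of the 4-month arrays (-14.0 to 1.96). This was already seen when a mislabelled age was considered, and the component was computed with this array included. A mislabelled age is therefore not excluded by it. Lower precision of the whole array stays open: its median absolute deviation from its group over precursors was the widest, which met the condition written beforehand, but it was only 1.016 times that of the next array. That lead lies within the spread of the other arrays, a margin required only after the value was seen. Over mature probe sets, where the array was seen to lie apart, its deviation was 0.183. The next widest were 0.164 in Clock 21-month replicate 3, which shares its group mean, and 0.150 in Clock 4-month replicate 1. In Clock 21-month replicate 2, the 19 probe sets that deviated most held 24.6% of the squared deviation over mature probe sets, against 15.0% to 19.5% in the other arrays. MIMAT0003482_st, singled out after its values were seen, stood at -6.60 in that array, with the next lowest Clock 21-month value at -0.93. No biological explanation was tested.

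Other splits of the arrays bear on the counts of calls. For age averaged over genotypes, 1 of 100 splits, the real one, gave as many as 2 calls and the highest other gave 1. That lead is 1 call, and the real count itself fell to 1 without Clock 4-month replicate 2. A chance division of the arrays is therefore not excluded. For the interaction and for genotype averaged over ages, 0 calls were observed, so all 100 splits give at least as many by construction and nothing follows about chance; another split gave up to 2 and 3 calls. The 10 splits of 3 against 3 are too few for a share under 0.05. As many calls came in 10 of 10 splits for genotype at each age, again by construction (real 0, highest other 1), in 1 for age in wild type (real 1, highest other 0), and in 2 for age in Clock (real 2, highest other 2).

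A hypothesis that earlier registered miRNAs, which have lower accession numbers, respond more to age was not borne out. They made up 51.4% of the probe sets with an unadjusted p under 0.05 for age averaged over genotypes, and 32 of 100 splits of the arrays gave as large a share.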
